A study of Folsomia candida with 8 samples.

How the data were processed

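RNA was measured in whole springtails of the species Folsomia candida, a small wingless soil arthropod that reproduces without males. The labels name 2 clones, TO1 and TO2, and 2 soils, one spiked with cadmium at 41.2 mg per kg and one not spiked, which gives 4 groups of 4 samples. Per the labels' protocols, each jar held about 30 animals aged 23 days on about 30 g of soil for 2 days at 20 °C, 75% humidity and a light period of 12 h. RNA came from all animals of a jar, and about 300 ng was labelled with Cy3 or Cy5. The labels call the samples of a group biological replicates, so the spread between samples is that between jars.

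The 16 samples were hybridised on 8 two-colour Agilent arrays of a custom design, and each sample was hybridised 1 time. In every group 2 samples carried Cy3 (replicates 1 and 2) and 2 carried Cy5 (replicates 3 and 4). The arrays, Cy3 sample first, paired TO1 control 1 with TO1 cadmium 3 on array 1 and TO1 cadmium 1 with TO2 control 3 on array 2. TO2 control 1 met TO2 cadmium 3 on array 3, and TO2 cadmium 1 met TO1 control 3 on array 4. On array 5, TO1 control 2 was set against TO2 control 4, and on array 6 TO2 control 2 against TO1 control 4. TO1 cadmium 2 and TO2 cadmium 4 shared array 7, and TO2 cadmium 2 and TO1 cadmium 4 shared array 8. The file headers place arrays 2, 6, 7 and 8 on 1 slide (slide 1), arrays 1, 3 and 5 on another (slide 2) and array 4 on its own (slide 3). Cadmium samples on slide 2 all carried Cy5.

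Per the file headers and the submitters' processing notes, the authors quantified each array with Agilent Feature Extraction 9.5.1.1, which wrote a mean spot intensity and a median local background intensity per dye on a linear scale, with no normalization. Feature Extraction also wrote processed intensities, background-subtracted and dye-normalized per the file headers, and a log10 ratio of Cy5 over Cy3 per spot. The authors also deposited a table of log2 ratios per spot, for which the submitters' processing notes name limma, with the method of normalization not given in the sources used here. Each column of that table correlated best with its own array's log10 ratio from the file (r 0.89 to 0.96, against at most 0.59 for any other array), with slopes of 0.94 to 1.09 on the log2 signal ratio, so its direction was taken as Cy5 over Cy3 and its scale as log2. Every column had a mean of 0. The column medians for arrays 1 to 8 were -0.04, 0.03, -0.05, 0.05, -0.04, 0.02, -0.03 and 0.07.

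Each array carried 15207 spots for 5069 probes, 3 spots per probe, and 536 control spots. The files give 1 probe per gene identifier, and the terms probe and gene are used for the same unit. A description of a database match accompanied 2321 probes, 1031 of them with the name of a protein, and 2748 had none. Names come from these descriptions, which rest on similarity to proteins of other species and are partly shortened. None of the identifiers matched the reference table of gene names (0 of 5069), so no genome position is given.

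Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and log ratios were normalized within each array by loess, with control and outlier spots at weight 0. The unflagged spots of a probe were averaged. A probe was tested when at least 2 of its 3 spots were well above background, by the scanner's flag, in 4 or more of the 16 channels, which left 4455 of 5069 probes. All spots of 13 tested probes were outliers on at least 1 array. These probes stayed in the fit with that array missing, which makes their standard errors approximate, and they were left out of the list tests. One limma model over all 8 arrays had a dye term and 3 coefficients for clone, soil and their interaction, with 4 residual degrees of freedom and a prior of 1.96. A gene was called when its moderated test gave an adjusted p under 0.05 (Benjamini-Hochberg over all genes tested). Fold changes carry the model's SE. Levels per sample are log2 values after loess and Aquantile normalization between arrays, given as mean ± SD. Differences of these levels need not equal the model's fold changes. Where a probe was not well above background in any sample of a clone, the fold is a bound. It sets the mean of the bright clone against the mean of, per sample, the higher of the lowest signal well above background and the probe's own value.

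The named genes were fixed by a rule set before the data were examined, as were the gene lists, the designs and most of the alternatives. For the cadmium effect, the clone effect and the interaction, the rule takes the 12 called genes with a protein name that had the largest positive and the 12 with the largest negative log2 fold change. It adds the 2 members with the lowest p of each list that passed its test. Names outside the rule are said to be chosen after their values were seen. Gene lists were 27 sets of words searched in the descriptions. Of these, 21 had at least 5 measured members and were tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists within a contrast), with an estimated correlation and with fry as alternatives. Of the 6 untested lists, metallothionein, which binds cadmium in many animals, had 0 probes under that name, and glutathione synthesis, glucuronosyl transferases, transposons, yolk and ovary, and DNA repair and cell cycle had 1, 2, 2, 3 and 4 measured members. The agreement of the cadmium effect between clones was set beside 100 simulations with no effect in the same design, with noise drawn independently for each gene.

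Signal over background was the measure of depth, and the number of arrays limits the precision. Between 80.3% and 89.2% of probes were well above background per channel, and the median signal was 4.83 to 22.2 times the median background. Within groups, levels of 2 samples correlated at r 0.93 to 0.99 across genes, and no 2 samples held identical values. In simulated data on 4442 genes with 100 changed by a log2 of 1 and 100 by a log2 of 2, the model recovered 78% and 98% for the averaged cadmium effect, 88% and 98% for the averaged clone effect, and 49% and 79% for the interaction. In the same simulation of lists, a list of 10 genes shifted by a log2 of 1 had an adjusted p of 3.5e-25, and 0 of 20 unshifted lists passed. The simulated genes were independent, so this does not show how often lists of correlated genes pass. In the data the estimated correlation was 0.54 for the glutathione S-transferases and 0.29 for the beta-lactam list.

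Alternatives covered no background correction, median centring in place of loess, the processed intensities, the authors' deposited log2 table, no filter on dim probes, a filter asking for all 16 channels, no dye term, separate-channel models with and without the replicate number as a block, array weights, eBayes with trend and robust settings, slide as a block, and each array left out in turn. Slide as a random block, slide as a block for the gene lists, lists without members that were not well above background in any sample of a group, and the joint removal of arrays 4 and 7 were added after seeing the data. Estimates within a slide used each gene's dye coefficient from all arrays, and slide as a block gave each slide its own dye term, with 2 residual degrees of freedom in place of 4. Within slide 2, cadmium in TO1, cadmium in TO2 and clone on control soil each came from a single array (1, 3 and 5). On each of these the cadmium or TO2 sample carried Cy5, so the value depends on the dye coefficient taken from all arrays. A test by probe in place of gene was not run apart, since each gene had 1 probe.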

Results

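Gene expression was compared between 2 clones of the springtail Folsomia candida, TO1 and TO2, kept for 2 days on soil spiked with cadmium, a toxic metal, or on soil not spiked. Each of the 4 groups had 4 samples, each a pool of animals from 1 jar. The 8 arrays gave values for 4455 genes above the detection filter, 889 of them with a protein name and 2090 with any database match. The median signal was 4.83 to 22.2 times background per sample, and TO2 cadmium sample 1 (22.2) stood apart from the other TO2 cadmium samples (4.98 to 7.60). The median background of that sample was 23, against 43 to 47 in the other samples in Cy3. The factorial design asked for the effect of clone, the effect of cadmium, and whether the clones differed in their response.

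Genes described as enzymes of beta-lactam antibiotic synthesis had the largest rises on cadmium soil among genes with a protein name. Isopenicillin N synthetase, the enzyme that closes the ring of penicillins in fungi and bacteria, was represented by 2 called probes. Fcc00057 was 11.5-fold higher on cadmium soil (log2 3.52 ± 0.51 SE, 8 against 8 samples, adjusted p = 0.0374) and Fcc01821 was 8.03-fold higher (log2 3.01 ± 0.42, adjusted p = 0.0374). The alpha-aminoadipyl-cysteinyl-valine (ACV) synthetase Fcc00170, which joins the 3 amino acids that isopenicillin N synthetase uses, was 10.1-fold higher (log2 3.34 ± 0.55, adjusted p = 0.0409). The lowest cadmium sample lay above the highest control of its clone in all of these genes. For Fcc00057 the highest TO1 control was at 11.79 and the lowest TO1 cadmium sample at 13.82, and in TO2 the same values were 11.53 and 12.88 (log2 levels). A short-chain dehydrogenase or reductase, Fcc05644, rose 5.78-fold (log2 2.53 ± 0.28, adjusted p = 0.0299), from 7.67 ± 0.06 to 11.12 ± 0.81 in TO1 and from 8.12 ± 0.26 to 10.17 ± 0.48 in TO2 (mean ± SD, n = 4).

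**Figure D1:**
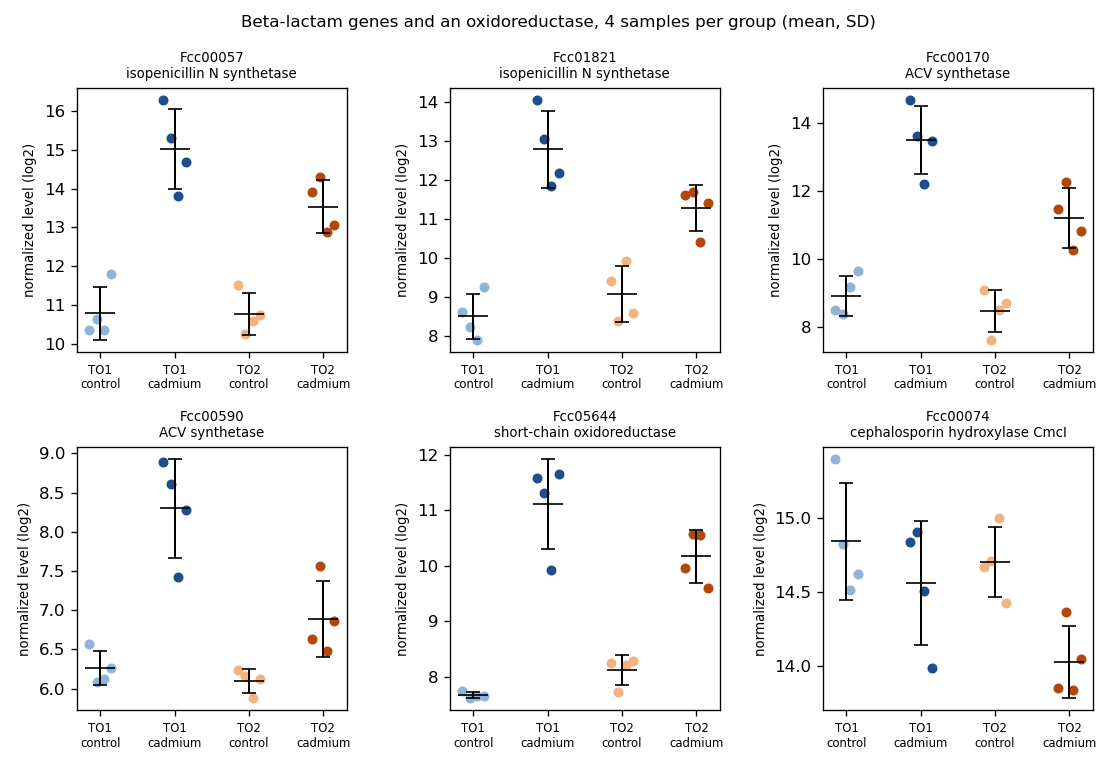
Normalized log2 level of 5 genes with descriptions of beta-lactam synthesis and of the oxidoreductase Fcc05644 in every sample, by clone and soil; points are samples, the horizontal mark is the mean of 4 and the bar its SD. In Fcc00057, Fcc01821 and Fcc00170 every cadmium sample lies above every control of its clone, while CmcI (Fcc00074) has lower means on cadmium soil, with overlapping samples in TO1.

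Other called rises among genes with a protein name were smaller. A DBH-like monooxygenase (Fcc00217) had a log2 change of 1.95 ± 0.33 and a protein described as actinohivin, a sugar-binding protein first known from bacteria (Fcc01646), one of 1.86 ± 0.29. A whey acidic protein domain gene (Fcc01910) rose by 1.45 ± 0.20, a fibrinogen C domain gene (Fcc00201) by 1.37 ± 0.22 and PAPI I (Fcc00311) by 1.05 ± 0.22. Copine 7 (Fcc01998), of a family of calcium-dependent membrane-binding proteins, rose by 1.00 ± 0.19, a transthyretin-like gene (Fcc02076) by 0.90 ± 0.17, and a beta-lactamase (Fcc01834), of the enzyme class that opens the beta-lactam ring, by 1.00 ± 0.16. The adjusted p of these 8 genes lay between 0.0374 and 0.0495.

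Called falls on cadmium soil were below 2-fold among the genes with a protein name. The helicase RecQ4 (Fcc01738) fell by 0.61 ± 0.11 on the log2 scale, BRCA1 (Fcc03637), a DNA repair protein, by 0.59 ± 0.10, a DNA mismatch repair protein (Fcc02956) by 0.51 ± 0.09 and MCM6 (Fcc03168), a subunit of the replicative helicase, by 0.48 ± 0.08, each with an adjusted p of 0.0409. The list for DNA repair and the cell cycle had 4 measured members and was not tested. Beside MCM6 they were topoisomerase II (Fcc02395, log2 -0.53, adjusted p = 0.0685), the cyclin-dependent kinase subunit 85A (Fcc02995, log2 -0.50, adjusted p = 0.0713) and topoisomerase I (Fcc06037, log2 -0.08, adjusted p = 0.452). The largest fall among the named genes was that of an SEC14-like protein, TAP3 (Fcc01091, log2 -0.91 ± 0.19). The homeobox gene Msx1 (Fcc05362, log2 -0.67 ± 0.07) and Su(var)205 (Fcc02794, log2 -0.66 ± 0.11), a heterochromatin protein in flies, were also lower. So were an AAA ATPase (Fcc06125, log2 -0.66 ± 0.08), importin alpha 2 (Fcc00649, log2 -0.64 ± 0.11), a carrier of nuclear import, an S-adenosyl methyltransferase (Fcc03809, log2 -0.57 ± 0.08), and brain tumor (Fcc00956, log2 -0.57 ± 0.12), a translational repressor in flies. The adjusted p of these 7 genes lay between 0.029 and 0.0491.

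The beta-lactam list had 8 measured members, of which 7 were higher and 1 lower on cadmium soil, with a median log2 change of 0.89 (camera adjusted p = 0.0158). With an estimated correlation the list's adjusted p was 0.759. Over all genes tested, 3 members were called higher and 1 lower, and adjusted over the list alone all 8 passed, 7 of them higher. The member called lower was the cephalosporin hydroxylase CmcI (Fcc00074, log2 -0.64 ± 0.12, adjusted p = 0.0429), an enzyme that modifies cephalosporins in bacteria. The list's median was 1.46 within slide 1, 0.75 within slide 2 and 0.70 with slide as a block, where it did not pass (adjusted p = 0.208). The glutathione S-transferases, enzymes that couple glutathione to reactive compounds, had 15 of 16 members higher (median log2 0.30, camera adjusted p = 0.019, and adjusted p = 0.759 with an estimated correlation). No glutathione S-transferase was called over all genes tested, and 3 passed adjusted over the list alone. The 2 with the lowest p were Fcc01282 (log2 0.60 ± 0.14, adjusted p = 0.0627) and Fcc02849 (log2 0.36 ± 0.09, adjusted p = 0.0701). The list's median was 0.14 within slide 1, 0.17 within slide 2 and 0.24 with slide as a block (adjusted p = 0.165). Without array 4 its adjusted p was 0.429, with median centring 0.0878 and in the separate-channel model 0.0782. Without the 3 members of each list that were not well above background in any sample of at least 1 group, the adjusted p was 0.14 for the beta-lactam list and 0.0812 for the glutathione S-transferases. By fry, which asks whether a list's genes move one way on balance, it was 0.0509 and 0.215. Without array 3 both lists stood at 0.0611, and without arrays 4 and 7 together they stood at 0.498 and, for the beta-lactam list, 0.0794.

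The other 19 lists did not pass for cadmium. Among them the heat shock list had 8 of 10 members higher (median log2 0.14, adjusted p = 0.14), the antioxidant list 12 of 13 (0.22, adjusted p = 0.14), the lipid list 16 of 18 (0.27, adjusted p = 0.14) and the cytochrome P450 list 10 of 12 (0.12, adjusted p = 0.281). Ribosomal proteins (21 of 35 higher, median 0.07, adjusted p = 0.509) and the gut marker lists of proteases (7 of 11, 0.36, adjusted p = 0.238) and carbohydrases (7 of 10, 0.16, adjusted p = 0.664) did not pass either. Of the markers of other tissues, the muscle list had 7 of 8 members higher (0.18, adjusted p = 0.154), the nerve list 5 of 10 (0.15, adjusted p = 0.485) and the immune list 2 of 5 (median -0.001, adjusted p = 0.664, with a mean of 0.28). Sequences named after bacteria or yeast were higher in 6 of 12 cases (0.10, adjusted p = 0.664). The 8 lists for ABC transporters, the proteasome, lysosomes, the cuticle, translation factors, respiration, central carbon metabolism and signalling kinases had medians between 0.004 and 0.26 and adjusted p from 0.14 to 0.704, with a mean below 0 for the cuticle (-0.09) and the ABC transporters (-0.02). Over all genes tested 2 members of the 19 lists were called, named after their values were seen. They were an inter-alpha-trypsin inhibitor relative in the protease list (Fcc01478, log2 0.80 ± 0.14, adjusted p = 0.0409) and a myosin 2 light chain in the muscle list (Fcc01638, log2 0.57 ± 0.08, adjusted p = 0.0374). Adjusted over the list alone, 5 members passed for lysosomes (4 of them higher), 3 for nerve, 2 for ABC transporters, 1 for proteases, 1 for muscle and 0 for the other 14.

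Averaged over the clones, 254 genes were called for cadmium, 138 higher and 116 lower, and 155 of them had no database match. The lean depended on the processing. It was 149 higher and 94 lower with median centring, 159 and 195 from Agilent's processed signals, and 158 and 301 from the authors' value table. All 254 had the same sign on slides 1 and 2, on which they were also selected, and the 2 slides' estimates correlated across genes at r = 0.53, while slide 3 held 1 array and gave no estimate. With slide as a block 0 genes were called (343 at an unadjusted p under 0.05). The median SE of the 254 genes, which were chosen in the main fit, went from 0.11 to 0.25. Their median size was 0.67 before and 0.70 after, and residual degrees of freedom went from 4 to 2. The count was also 0 without array 1, 2, 4, 7 or 8, and without arrays 4 and 7 together, it was 59 without array 5, and it was 1017 with array weights and 1049 in the separate-channel model. The weights, estimated from the same arrays, ran from 0.21 for array 4 to 2.84 for array 1.

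Between the clones, the largest difference among genes with a protein name was 38.5-fold, and 3 genes described as antimicrobial peptides were among the named genes, 1 higher and 2 lower in TO2. Higher in TO2 were a 3-hydroxyisobutyrate dehydrogenase (Fcc01235, 38.5-fold, log2 5.27 ± 0.23, 8 against 8 samples, adjusted p = 8e-05), an enzyme of valine breakdown, a granulin-like growth factor gene (Fcc00593, 15.4-fold, log2 3.95 ± 0.17, adjusted p = 8.11e-05, well above background in 6 of 8 TO1 samples) and the antimicrobial peptide Alo2 (Fcc05968, 9.85-fold, log2 3.30 ± 0.36, adjusted p = 0.00355). The last stood at 9.40 ± 0.70 and 10.81 ± 0.59 in TO1 on control and cadmium soil and at 13.24 ± 0.55 and 13.88 ± 0.76 in TO2 (mean ± SD, n = 4). Lower in TO2 were an alpha-tectorin-like gene (Fcc05235, 19.9-fold, log2 -4.31 ± 0.37, adjusted p = 0.00127), theromacin (Fcc05207, 17.0-fold, log2 -4.08 ± 0.12, adjusted p = 2.44e-05), an antimicrobial peptide known from leeches, and spodomicin (Fcc04856, 8.54-fold, log2 -3.09 ± 0.13, adjusted p = 7.27e-05), one known from moths. A heat shock protein 70 gene (Fcc02719), a chaperone of stressed cells, was 5.15-fold lower in TO2 (log2 -2.37 ± 0.15, adjusted p = 0.000326). It stood at 8.82 ± 0.36 and 10.09 ± 0.40 in TO1 and at 6.96 ± 0.09 and 7.37 ± 0.23 in TO2.

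**Figure D2:**
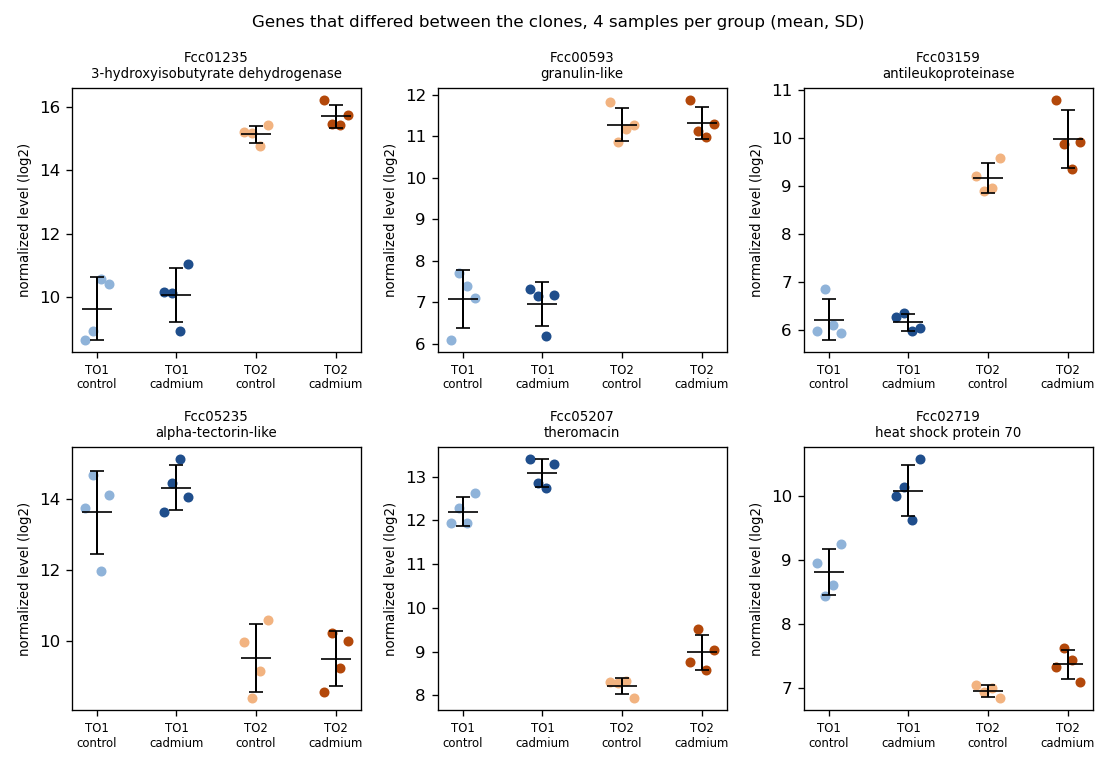
Normalized log2 level of 6 genes called between the clones in every sample, by clone and soil; points are samples, the horizontal mark is the mean of 4 and the bar its SD. Fcc01235, granulin-like Fcc00593 and antileukoproteinase Fcc03159 lie higher in all TO2 samples, and alpha-tectorin-like Fcc05235, theromacin Fcc05207 and heat shock protein 70 Fcc02719 lie lower.

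Of the 12 named genes with the largest values in TO2, 4 were well above background in all 8 TO2 samples and in none of the 8 TO1 samples. These were antileukoproteinase (Fcc03159, at least 8.90-fold, adjusted p = 7.27e-05), a protease inhibitor, a neurite outgrowth regulated kinase (Fcc03313, at least 4.46-fold, adjusted p = 9.18e-05), an ADAM 33 metallopeptidase (Fcc00971, at least 3.92-fold, adjusted p = 0.00408) and a Tat-interactive protein (Fcc02227, at least 3.60-fold, adjusted p = 1.31e-05). Fasciclin II (Fcc00863), a cell adhesion protein, was higher in TO2 by a log2 of 3.00 ± 0.39. A flavoprotein (Fcc00543) was 5.21-fold higher, a UDP-glucuronosyltransferase (Fcc04872) 3.81-fold, CD63 (Fcc06041) 3.78-fold and a pancreatic lipase relative (Fcc02519) 3.38-fold, and the adjusted p of these 5 genes lay between 9.09e-05 and 0.0182. Lower in TO2 were a transposase (Fcc01290, 3.75-fold), a Krueppel-related zinc finger gene (Fcc04413, 2.29-fold), a valosin-containing protein relative (Fcc04558, 2.00-fold), casein kinase I (Fcc05004, 1.96-fold), the beta-lactamase Fcc01834 (1.89-fold), arginyl-tRNA synthetase (Fcc00468, 1.83-fold), a phosphatidylinositol transfer protein (Fcc03344, 1.59-fold) and a lymphocyte cytosolic protein relative (Fcc01117, 1.52-fold), with adjusted p between 6.82e-05 and 0.0424.

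On the whole array, 49 probes were well above background in every TO2 sample and in no TO1 sample, and 0 were so in the other direction. All 49 were called, the median of their bounds was at least 2.97-fold and 37 had no database match. For the soils, 1 probe was well above background in every cadmium sample and in no control sample (Fcc04031, with no match, at least 3.62-fold, named after its values were seen), and 0 in the other direction.

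Among the lists, the glutathione S-transferases had 14 of 16 members higher in TO2 (median log2 0.21, camera adjusted p = 0.0468, and adjusted p = 0.803 with an estimated correlation). Of these 3 were called, and 4 passed adjusted over the list alone. Fcc06274 was well above background in all TO2 and no TO1 samples (at least 2.51-fold, adjusted p = 0.000235). Fcc00851 was so in 7 of 8 TO2 samples and no TO1 sample (at least 1.24-fold, adjusted p = 0.035), and the third, named after its values were seen, was Fcc05260 (log2 0.60 ± 0.13, adjusted p = 0.0458). The list's median was 0.04 within slide 1, 0.26 within slide 2 and 0.14 with slide as a block (adjusted p = 0.223). Its adjusted p was 0.107, 0.0696, 0.314 and 0.0508 without arrays 2, 3, 4 and 7, 0.675 without arrays 4 and 7 together, 0.0856 with no filter on dim probes, 0.0789 in the separate-channel model, 0.2 without the 3 members at background in a group, and 0.18 by fry. The immune list had 3 of 5 members higher, all 3 called, with a median of 1.59 that did not pass camera (adjusted p = 0.223) and passed fry (adjusted p = 0.00197), which does not compare a list with other genes. Adjusted over the list alone, 4 members passed, 3 of them higher. Its called members were Alo2 and, named after their values were seen, lectin 2a (Fcc00508, log2 1.59 ± 0.28) and a peptidoglycan deacetylase (Fcc04902, log2 1.73 ± 0.12). The deacetylase is in the list by the words of its description alone, which do not show an immune role, so the list's result rests in part on it. The list's words did not pick up theromacin (Fcc05207, log2 -4.08) or spodomicin (Fcc04856, log2 -3.09), both called lower in TO2. The list's direction therefore does not cover these antimicrobial peptides. The heat shock list had 6 of 10 members higher, with a median of 0.09, a mean of -0.13 and an adjusted p of 0.994. Beside Fcc02719, its called members, named after their values were seen, were a DnaJ domain gene (Fcc01714, log2 -0.30, adjusted p = 0.0316) and a heat shock protein gene (Fcc05278, log2 0.65, adjusted p = 0.0288), and the same number, 3, passed adjusted over the list alone.

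**Figure D3:**
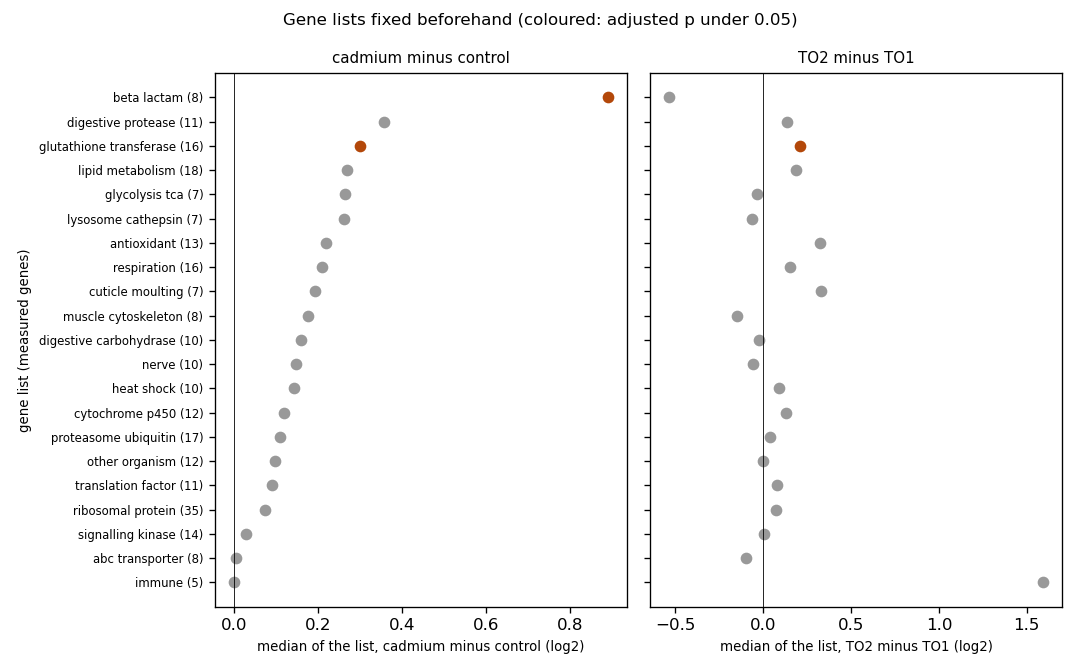
Median log2 change of each tested gene list for cadmium minus control (left) and TO2 minus TO1 (right), with the number of measured genes in brackets; coloured points have an adjusted p under 0.05 by camera at the preset correlation. For cadmium the beta-lactam list (0.89) and the glutathione S-transferases (0.30) pass, and for clone the glutathione S-transferases (0.21), and none of these passes with an estimated correlation (adjusted p = 0.759, 0.759 and 0.803).

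The other 18 lists did not pass camera for clone. The muscle list had 7 of 8 members lower in TO2 (median -0.15, adjusted p = 0.0666), the beta-lactam list 7 of 8 lower (-0.53, adjusted p = 0.0666) and the antioxidant list 11 of 13 higher (0.32, adjusted p = 0.0666). The respiration list was higher in 12 of 16 members (0.15, adjusted p = 0.303 by camera and 0.00886 by fry) and ribosomal proteins in 26 of 35 (0.07, adjusted p = 0.303). Called members, named after their values were seen, were the myosin 2 light chain Fcc01638 (log2 -0.59 ± 0.07), thioredoxin (Fcc04514, log2 0.76 ± 0.15), and the respiration genes ATP synthase subunit 6 (Fcc00661, log2 0.87 ± 0.16) and cytochrome c oxidase subunit II (Fcc01457, log2 0.61 ± 0.11). Adjusted over the list alone, 1 member passed for muscle, 1 for the antioxidant list, 3 for respiration, 5 for the beta-lactam list (1 of them higher) and 0 for ribosomal proteins. The beta-lactam list's median was -0.69 within slide 1, 0.02 within slide 2 and -0.76 with slide as a block (adjusted p = 0.145). The other 13 lists had medians between -0.10 and 0.33 and adjusted p from 0.235 to 0.994, with 0 to 3 members each passing adjusted over the list alone. Means and medians differed in sign for carbohydrases (0.13 and -0.02), central carbon metabolism (0.11 and -0.04) and sequences named after bacteria or yeast (0.06 and -0.001).

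Averaged over the soils, 400 genes were called between the clones, 280 higher in TO2 and 120 lower, and 126 of them by over 2-fold. On slides 1 and 2, 392 of the 398 that both slides could estimate had the same sign, with r = 0.73 across all genes. With slide as a block 119 genes were called, and the count was 225 among probes detected in all 16 channels, 236, 167, 209 and 171 without arrays 1, 2, 5 and 7, and 154 without arrays 4 and 7 together.

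Within clone TO1, 78 genes were called for cadmium, 39 higher and 39 lower, and 77 of these were among the 254 of the averaged effect, which includes TO1. Isopenicillin N synthetase was 16.8-fold higher in TO1 for Fcc00057 (log2 4.07 ± 0.66, 4 against 4 samples, adjusted p = 0.0492) and 12.5-fold for Fcc01821 (log2 3.65 ± 0.54, adjusted p = 0.0481). In TO2 the same genes had log2 changes of 2.97 ± 0.66 and 2.36 ± 0.54, with adjusted p of 0.201 each. In TO2 0 genes were called by limma's log-ratio model, with 741 at an unadjusted p under 0.05 and 112 called by the separate-channel model. The beta-lactam list passed in TO1 (7 of 8 higher, median 1.24, adjusted p = 0.00722, and 0.79 as adjusted p with an estimated correlation), with 2 members called and 8 passing adjusted over the list alone, 7 of them higher. Its median in TO1 was 1.67 within slide 1, 0.97 within slide 2 and 1.05 with slide as a block (adjusted p = 0.164). The adjusted p was 0.0712 without arrays 4 and 7 together, 0.108 without the 3 members at background in a group, and 0.1 by fry. In TO2 the list had 7 of 8 members higher and did not pass (median 0.55, adjusted p = 0.0739). The glutathione S-transferases had 14 of 16 members higher in TO1 (median 0.34, adjusted p = 0.0496, and adjusted p = 0.79 with an estimated correlation), none called over all genes tested and 3 adjusted over the list alone, led by Fcc01881 (log2 0.54 ± 0.12, adjusted p = 0.0611) and Fcc02849 (log2 0.47 ± 0.12, adjusted p = 0.077). Their median in TO1 was 0.11 within slide 1, 0.19 within slide 2 and 0.37 with slide as a block (adjusted p = 0.114). Their adjusted p there was 0.0845, 0.333, 0.0578, 0.0593 and 0.195 without arrays 3, 4, 5, 7 and 8 and 0.203 without arrays 4 and 7 together. It was 0.309 with median centring, 0.0987 with Agilent's processed signals, 0.0654 with no filter on dim probes, 0.0567 with no background correction, 0.117 in the separate-channel model, 0.108 without the 3 members at background in a group, and 0.308 by fry. In TO2, 15 of 16 were higher (median 0.25, adjusted p = 0.0739). The count of 78 in TO1 was 0 with slide as a block (407 at an unadjusted p under 0.05), 0 without array 1, 2, 4, 7 or 8, 2 without array 5, 269 without array 3 and 230 without array 6, and 706 with median centring. Most calls with median centring, from Agilent's processed signals and from the authors' value table were lower on cadmium soil, unlike the even split here.

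**Figure D4:**
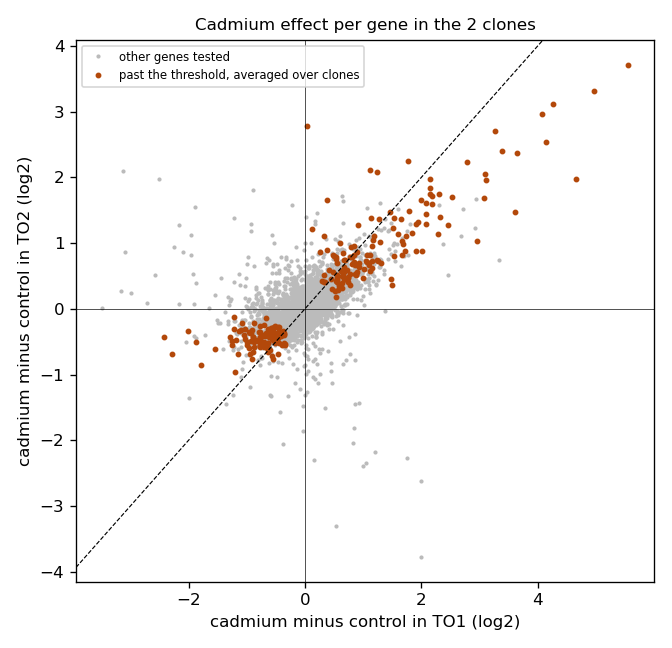
Cadmium minus control (log2) per gene in TO1 (horizontal) and TO2 (vertical) for the 4455 genes tested; coloured points passed the threshold for the effect averaged over the clones and the dashed line marks equal effects. All 254 coloured genes have the same sign in both clones, and 210 are larger in TO1. Selection on the average of the clones favours genes with the same sign in both.

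The test of the difference between the clones' responses called 0 genes (360 at an unadjusted p under 0.05, and 17 called by the separate-channel model). In all 8 members of the beta-lactam list the cadmium effect in TO2 minus that in TO1 was below 0 (median difference -0.73, camera adjusted p = 0.0214, and adjusted p = 0.937 with an estimated correlation). None was called singly, over all genes or adjusted over the list alone. The 2 with the lowest p were the isopenicillin N synthase relative Fcc05602 (difference -0.47 ± 0.17, adjusted p = 0.582) and an ACV synthetase, Fcc00590 (adjusted p = 0.612), for which no size is given, as 0 of 4 TO1 controls and 1 of 4 TO2 controls were well above background. In 2 further members, Fcc04493 and Fcc04939, no control of either clone was well above background, so the differences of these 3 members are limited by the floor. The other 5 had a median difference of -1.10 and did not pass as a list (adjusted p = 0.211). They include CmcI (Fcc00074), with log2 changes of -0.63 in TO1 and -0.66 in TO2. The list's median difference was -0.03 within slide 1, -0.62 within slide 2 and -0.67 with slide as a block (adjusted p = 0.308). The list's adjusted p was 0.213, 0.101, 0.453 and 0.139 without arrays 3, 4, 5 and 7, 0.177 without arrays 4 and 7 together, 0.426 with median centring and 0.897 by fry. No other list passed (lowest adjusted p 0.684).

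Cadmium effects in the 2 clones were correlated across genes, which are not independent replicates, at r = 0.58 and rho = 0.65. With no effect simulated in the same array loop, r was 0.20 on average and at most 0.34, and rho 0.18. The simulations drew each gene's noise independently, so their ranges leave out any noise that genes share on an array. The covariance was 0.136 against 0.0230 in the simulations, and 75.3% of genes had the same sign against 56.5%. Within slides the correlation was 0.74 on slide 1, where the clones' effects share arrays, and 0.18 on slide 2, where they come from different arrays. Of the 78 genes called in TO1, all 78 had the same sign in TO2 and 76 were larger in TO1 (median size 1.25 against 0.57), a set chosen for its size in TO1.

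The difference between the clones was called for 146 genes on control soil (117 higher in TO2, 29 lower) and for 241 on cadmium soil (183 higher, 58 lower). The 2 sets shared 129 genes, all in the same direction, against 5.18 in the same direction for independent lists, although part of the excess may come from the arrays that both contrasts use in the fit. On control soil the glutathione S-transferases passed (15 of 16 higher, median 0.28, adjusted p = 0.0109, and adjusted p = 0.943 with an estimated correlation), with 1 member called over all genes and 1 adjusted over the list alone. That member was Fcc06274 (at least 2.23-fold, adjusted p = 0.00245), and Fcc00851 was well above background in 3 of 4 TO2 controls (at least 1.18-fold, adjusted p = 0.16). On cadmium soil the beta-lactam list was lower in TO2 in 7 of 8 members (median -0.96, adjusted p = 0.0224, and adjusted p = 0.916 with an estimated correlation), with 0 called over all genes and 4 adjusted over the list alone. Its members with the lowest p were the ACV synthetases Fcc00590 (log2 -1.34 ± 0.27, adjusted p = 0.0513) and Fcc00170 (log2 -2.40 ± 0.64, adjusted p = 0.0996). Within slides 1 and 2 the median of the glutathione S-transferases on control soil was 0.02 and 0.36, and that of the beta-lactam list on cadmium soil -0.83 and -0.19. With slide as a block the former was 0.22 (adjusted p = 0.105) and the latter -1.01 (adjusted p = 0.0483). The former's adjusted p was 0.201 without array 4, 0.235 without arrays 4 and 7 together, 0.185 with median centring, 0.144 without the 3 members at background in a group, and 0.383 by fry. The latter's was 0.0818 without array 3, 0.052 without array 4, 0.0723 without arrays 4 and 7 together, 0.0523 with no filter on dim probes, 0.218 without the 3 members at background in a group, and 0.106 by fry. The immune list passed fry on control and cadmium soil (adjusted p = 0.0123 and 0.00602) and the respiration list on cadmium soil (adjusted p = 0.0208), and neither passed camera there. On control soil the count was 36 with slide as a block and 76, 85, 79 and 82 without arrays 1, 2, 5 and 6, and median centring turned the split to 104 higher and 123 lower. On cadmium soil it was 164 with slide as a block and 116, 123, 98 and 128 without arrays 1, 2, 7 and 8.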

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

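Of the tests in this part, those of an array fault, of weak signal among bright genes, of the other clone and of the control soil for the genes low in TO2 cadmium samples 1 and 4, were chosen only after the result was seen.

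The 49 probes that were well above background in all 8 TO2 samples and in none of the 8 TO1 samples, against 0 the other way, were counted on the scanner's own calls, which are made before normalization. In TO2 they lay at a median log2 of 1.69 above the mean detection floor of the TO2 channels (lower quartile 1.14). The choice of probes puts them above that floor, but does not set the distance. For probes far above it, the distance argues against a lower sensitivity of the TO1 channels, whose floors were 6.22 to 6.48, against 6.05 to 6.47 in TO2 (log2). For probes near it, with bounds down to 1.23-fold, lower sensitivity stays open. A median of 82.9% of probes were well above background in TO1 samples against 86.0% in TO2. A strain variant against the array's probe sequences, which would weaken hybridisation in 1 clone, stays open, and it would shift other probes the same way. Among the 274 genes called between the clones and well above background in all 16 channels, 59.9% were higher in TO2 (164 genes, exact 95% interval 53.8% to 65.7%), consistent with such a shift. A difference in expression between the clones could give the same share and stays open too.

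Genes far below the rest of their group in TO2 cadmium samples 1 and 4 stood out in the values per sample. Of genes at least 16-fold below the median of the other 3 samples of their group, sample 1 had 22 and sample 4 had 6, against at most 7 in the other 14 samples, and 5 genes were low in both (0.0297 expected, exact hypergeometric p = 1.1e-11). That p treats genes as independent and as equally variable. The share of all probes well above background was 86.8% in sample 1, which meets the bound set beforehand (1 of the 2 samples above the median of 83.2%), but 82.7% in sample 4, for which that bound was wrong as it leaves weak signal there open, while of genes as bright in the other 3 samples as those low here at least 99.8% were well above background in both, which argues against it, as 98% or more of 50 clone-specific probes does against samples of the other clone. For the 5 genes low in both, samples of the control soil are argued against, as each lay at least 2.91 (log2) below the lowest TO2 control (control ranges up to 1.75), and so is a fault of one array or slide, as samples 1 and 4 lie on different arrays, slides and dyes, while for the genes low in 1 sample both stay open, since of the 17 low in sample 1 only, 14 lay below the lowest TO2 control but 5 by more than the control range, since 65.2% and 66.7% of 69 genes chosen without samples 1 and 4 lay nearer the cadmium than the control mean, between the outcomes set for either case, and since the count of 6 in sample 4 was not above that of every other sample. For these 5 (Fcc00151, Fcc01585, Fcc01688, Fcc04350 and Fcc04721, chosen after their values were seen, 4 with no match) the median levels were 6.95 and 6.86, against 12.46 and 14.14 in TO2 cadmium samples 2 and 3 and 12.96 to 14.32 in the TO2 controls, and no biological explanation was tested. The 5 also varied widely among the TO1 controls (log2 levels). Fcc00151 ran from 10.98 to 14.05, Fcc01585 from 8.3 to 12.04 and Fcc01688 from 11.08 to 14.94. The range was 11.06 to 16.3 for Fcc04350 and 9.26 to 15.65 for Fcc04721.

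A sample far from the other 3 of its group was found in 16 of 224 groups checked, where chance gives about 1 in 20, by a gap to the nearest sample, as a share of the group's range, above Dixon's 95% limit. TO2 cadmium sample 1 had the highest median signal over background of its group (22.2, the others 4.98 to 7.60, gap 0.848 of the range). Its median background was 23, against 43 to 47 in the other Cy3 samples. Its median signal was 510, against 350 in TO2 cadmium sample 2 and 508 in TO2 control sample 1, both also in Cy3. The same sample was high for the transthyretin-like gene Fcc02076 (12.70 against at most 12.18, log2, gap 0.968) and the mismatch repair gene Fcc02956 (10.14 against at most 9.46, gap 0.832), and low for MCM6 Fcc03168 (9.20 against at least 9.57, gap 0.862). TO2 cadmium sample 2 was high for brain tumor Fcc00956 (12.23 against at most 11.91, gap 0.848) and for Fcc04558 (10.34 against at most 10.11, gap 0.884). TO2 control sample 2 was low for the oxidoreductase Fcc05644 (7.73 against at least 8.21, gap 0.856) and for actinohivin Fcc01646 (6.57 against at least 7.34, gap 0.893). In TO2 control sample 4 the low values were those of the AAA ATPase Fcc06125 (8.66 against at least 9.18, gap 0.881), brain tumor Fcc00956 (12.25 against at least 12.61, gap 0.898) and theromacin Fcc05207 (7.93 against at least 8.29, gap 0.896). In TO1, granulin-like Fcc00593 was low in cadmium sample 3 (6.19 against at least 7.16, gap 0.845), and the kinase Fcc03313 was low in cadmium sample 4 (5.79 against at least 6.16, gap 0.877). That kinase was not well above background in any TO1 sample, so its gap lies among background values. TO1 cadmium sample 4 was high for arginyl-tRNA synthetase Fcc00468 (11.33 against at most 11, gap 0.934). TO1 control sample 2 was high for ADAM 33 Fcc00971 (6.64 against at most 6.07, gap 0.886), and TO1 control sample 3 was low for the glutathione transferase Fcc01881 (7.83 against at least 8.38, gap 0.922). ADAM 33 was not well above background in any TO1 sample either.

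The beta-lactam list differed between the clones in its cadmium effect, lower in TO2 in 8 of 8 members, by the interaction test at the preset correlation (median difference -0.73, adjusted p = 0.0214; -0.03 within slide 1 and -0.62 within slide 2), and not with an estimated correlation (adjusted p = 0.937), with slide as a block (adjusted p = 0.308) or without the 3 members at background in a group (adjusted p = 0.211).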

How the results depend on the processing

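The tests with slide as a random block, with slide as a block for the gene lists, of lists without members at background in a group, and without arrays 4 and 7 together (TO2 cadmium samples 1 and 4) were chosen after the result was seen. The genes called in each contrast had the same sign under every setting that gave them a value. Of the values for the genes named, 332 of 570 for the averaged cadmium effect kept their side of the threshold, 233 no longer passed and 5 newly passed. For the clone effect 525 of 562 kept it and 37 no longer passed. For cadmium in TO1 these were 59 of 88, with 22 lost and 7 gained. For clone on control soil they were 37 of 42, with 1 lost and 3 gained, for clone on cadmium soil 32 of 43, with 11 gained, and for the interaction 43 of 43. The value that reversed was that of Fcc00851 for clone on control soil, -0.015 with median centring. Medians over all genes stayed within 0.06 of 0 (log2). With 8 arrays and 4 residual degrees of freedom, the number of arrays limits the precision, while 80.3% to 89.2% of probes were well above background.

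For the averaged cadmium effect (254 genes, 54.3% higher) the count was 459 from the authors' value table (158 higher and 301 lower, 34.4% higher), 108 with no dye term, 1049 from separate channels, 1017 with array weights, 0 with slide as a block (343 at an unadjusted p under 0.05) and 110 with slide as a random block. It was 0 to 285 with each array left out, 0 without arrays 1, 2, 4, 7 or 8 (745 to 1345 at an unadjusted p under 0.05), and 59 without array 5, and it was 0 without arrays 4 and 7 together (896 at an unadjusted p under 0.05). In the last, the median size of the 254 genes was 0.62 with a median SE of 0.12, against 0.67 and 0.11, and residual degrees of freedom were 2. With slide as a block the size was 0.70 and the SE 0.25.

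For the averaged clone effect (400 genes, 70% higher) the count was 225 among probes detected in all 16 channels, a filter that tests fewer genes, 881 from separate channels, 119 with slide as a block, 154 without arrays 4 and 7, and 167 to 378 with each array left out (236, 167, 209 and 171 without arrays 1, 2, 5 and 7). The authors' value table gave 487, 56.9% of them higher. The interaction had 0 genes in each run with limma's log-ratio model, 0 to 0 with each array left out (206 to 599 at an unadjusted p under 0.05), and 17 from separate channels.

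For cadmium in TO1 (78 genes, 50% higher) the count was 124 with no background correction, 706 with median centring (38.0% higher), 416 from Agilent's processed signals (36.5% higher), 418 from the authors' value table (28.5% higher), and 179 among probes detected in all 16 channels. It was 12 with no dye term, 1051 from separate channels, 1218 with array weights, 154 with trend and robust settings, 51 with slide as a random block, and 0 with slide as a block or without arrays 4 and 7 (407 and 1037 at an unadjusted p under 0.05). With each array left out it was 0 to 269, 0 without arrays 1, 2, 4, 7 or 8 (613 to 1119 at an unadjusted p under 0.05), 2 without array 5 (Fcc00343 and Fcc04580, chosen after their values were seen), 269 without array 3 and 230 without array 6. For cadmium in TO2 (0 genes) it was 4 with median centring (Fcc00343, Fcc03317, Fcc05180 and Fcc05311, all higher and chosen after their values were seen), 112 from separate channels and 0 to 0 with each array left out (354 to 975 at an unadjusted p under 0.05).

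For clone on control soil (146 genes, 80.1% higher) the count was 227 with median centring (45.8% higher), 51 among probes detected in all 16 channels, 495 from separate channels, 36 with slide as a block and 76 to 135 with each array left out (76, 85, 79 and 82 without arrays 1, 2, 5 and 6). The authors' value table had 69.8% higher. For clone on cadmium soil (241 genes, 75.9% higher) it was 89 among probes detected in all 16 channels, 694 from separate channels, 429 with array weights, 388 with slide as a random block, 101 without arrays 4 and 7 and 98 to 230 with each array left out (116, 123, 98 and 128 without arrays 1, 2, 7 and 8). The share higher from the authors' value table was 65.3%.

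Agreement of the Cd effect between clones (r = 0.577) was 0.444 with median centring, 0.391 without arrays 4 and 7, and 0.429 to 0.702 with each array left out. Of the gene list tests, 8 passed over the 7 contrasts, and 19 did with median centring, 5 with no filter on dim probes, 0 without arrays 4 and 7, 0 with an estimated correlation, and 0 without members at background in a group. The count was 2 to 11 with each array left out (2 without array 3 and 2 without array 4). With median centring 4 of the 8 and 15 others passed. With fry 0 of the 8 passed and 5 others did, the immune and respiration lists between the clones. With slide as a block 1 passed, the beta-lactam list for clone on cadmium soil. Apart from fewer genes tested, fewer samples or fewer residual degrees of freedom, the cause of these changes was not tested.

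The correlations between samples gave no sign that the replicate numbers pair them, which leaves a batch shared by number open. In all, 3 of 16 samples correlated best with a sample of their own number, and same-numbered samples had r from -0.218 to 0.341. With the replicate block, separate channels gave 1395 genes for the averaged cadmium effect, 1217 for the clone effect, 57 for the interaction, 1417 for cadmium in TO1, 322 for cadmium in TO2, 778 for clone on control soil and 931 for clone on cadmium soil.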

Other observations

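Of the tests in this part, that of the DNA replication and repair words and that of an exchange of TO1 samples were chosen only after the result was seen, as were the genes named in the next 3 paragraphs. The splits of the samples were planned.

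Among the genes of lists too small to test, vitellogenin I (Fcc05618), a yolk precursor protein, was higher on cadmium soil by a log2 of 0.81 ± 0.15 (adjusted p = 0.0439), with 1.02 in TO1 and 0.61 in TO2. The other measured yolk and egg membrane genes gave -0.19 (yolk polypeptide 2, Fcc02167, adjusted p = 0.307) and -0.02 (Fcc05544, adjusted p = 0.945). The glucuronosyl transferases UGT1A10 (Fcc01065) and Ugt86Da (Fcc02716) gave 0.52 (adjusted p = 0.204) and -0.09 (adjusted p = 0.543). The list's words did not pick up the UDP-glucuronosyltransferase Fcc04872, with cadmium effects of 0.35 ± 0.14 in TO1 and 0.37 ± 0.14 in TO2. The only measured member of the glutathione synthesis list was a methionine synthase reductase (Fcc02145, 0.11, adjusted p = 0.411). That name is not one of an enzyme of glutathione synthesis, so the value is no measure of that pathway. Of the transposon list, the transposase Fcc01290 and the Tcb2 transposase Fcc05687 gave 0.21 and 0.12 for cadmium (adjusted p = 0.183 and 0.411), and the latter -0.22 for clone (adjusted p = 0.143).

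Of 8 probes described as genes of the mitochondrial genome, 6 had a higher and 2 a lower estimate in TO2, and 2 were called. Subunit 6 of ATP synthase was higher in TO2 by a log2 of 0.87 ± 0.16 (Fcc00661, adjusted p = 0.0254), and a second probe of that name gave 0.57 (Fcc04261, adjusted p = 0.062). Cytochrome c oxidase subunit II was higher by 0.61 ± 0.11 (Fcc01457, adjusted p = 0.0223). NADH dehydrogenase subunit 4 gave -0.61 (Fcc04995, adjusted p = 0.0929), subunit 5 -0.37 (Fcc00793, adjusted p = 0.219) and subunit 4L 0.20 (Fcc00588, adjusted p = 0.51), while cytochrome b gave 0.07 (Fcc00671, adjusted p = 0.74) and cytochrome oxidase subunit 1 0.15 (Fcc03493, adjusted p = 0.331).

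The largest called changes fell on genes without a protein name. For cadmium these were Fcc00343, described as a hypothetical protein (log2 4.63 ± 0.39, adjusted p = 0.029), and Fcc04207 (log2 4.14 ± 0.41, adjusted p = 0.029). For clone they were Fcc04198 (log2 7.005 ± 0.111, adjusted p = 5.28e-06) and Fcc01582 (log2 6.96 ± 0.18), both well above background in 6 of 8 TO1 samples and in all 8 TO2 samples.

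Of the 12 named genes with the largest falls on cadmium soil, 4 have roles in DNA replication or repair, and a hypothesis is that genes with such descriptions fell together. A list of words for DNA replication, repair and mitosis held 16 genes, 14 of them lower, with a median log2 of -0.30 and a p of 0.000114 by limma's camera, not adjusted as 1 list was tested. These 16 include the 4 genes that prompted the list. Without them, 10 of the remaining 12 were lower, with a median of -0.12. Their camera p was 0.00823, with all called genes also taken out of the genes they were compared with. The tests of the 12 that follow used the same reduced comparison, in which a small joint shift stands out more. The median of the 12 was -0.28 within slide 1, -0.11 within slide 2 and -0.16 with slide as a block, where the p was 0.0315. With an estimated correlation (0.0630) their p was 0.0989, and that of all 16 was 0.0792. The values without the 4 genes are consistent with a joint fall at the preset correlation, and the call is not held with the estimated correlation.

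Other splits of the samples gave as many called genes as the real one in 2 of 100 splits for the averaged cadmium effect (254 genes, highest other 1072) and in 1 of 100 for the averaged clone effect (400, highest other 18), the real split included. Both shares were below the bound set beforehand. The splits hold neither dye nor slide fixed. Among them chance is argued against for the clone effect. For cadmium they do not decide the question, as such splits mix chance with dye and slide. The highest other split for cadmium sets 6 Cy5 samples against 2, and with slide as a block the averaged cadmium count was 0 by limma (343 at an unadjusted p under 0.05). Among such splits chance is also argued against for clone on control soil (1 of 34 splits, 146 genes, highest other 0) and on cadmium soil (1 of 34, 241, highest other 32), and 1 further split of each could not be fitted. Chance is not excluded for cadmium in TO1 (2 of 35, 78 genes, highest other 616). For the interaction (highest other 821) and cadmium in TO2 (highest other 5) the real count was 0, which every split reaches (100 of 100 and 35 of 35), so the splits say nothing of chance there. The highest other splits for the averaged cadmium effect and cadmium in TO1 called several times the real count, and the reason was not found. Both exchange, up to a mirror of the groups, TO1 control sample 4 and TO1 cadmium sample 2, both on slide 1. In TO1 that split sets 1 Cy5 sample against 3, where the real split is balanced, and like the real split it sets 1 slide-1 sample against 3. With slide as a block the real count in TO1 was 0 by limma (407 at an unadjusted p under 0.05). An exchange of the labels of these 2 samples is argued against by 46 genes chosen without them, from TO2 and the other TO1 samples, of which 100% in TO1 cadmium sample 2 and 93.5% in TO1 control sample 4 lay nearer the mean of the labelled group.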
